A study of Rattus norvegicus with 20 samples.

How the data were processed

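Prefrontal cortex was taken on postnatal day 0 from Sprague-Dawley rats, an outbred laboratory strain, whose dams had received valproic acid (VPA) or saline on gestation day 12.5. VPA is an antiepileptic drug and histone deacetylase inhibitor, and prenatal exposure to it in rodents is used as a model of autism. Per the labels' protocols, VPA was given at 500 mg/kg from a 250 mg/mL solution in 0.9% saline, and control dams received the same volume of saline by weight. Biotin-labelled cRNA was made from 500 ng of total RNA by the Affymetrix protocol, per the labels. The 20 arrays fell into 4 groups of 5 by sex and exposure, called male saline, male VPA, female saline and female VPA, and each array was numbered within its group by the labels as a biological replicate.

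The values used were the authors' deposited log2 signals, 1 column per array, for 29489 probe sets. The background correction, summarization and normalization that made them are not given in the sources used here. The scale was read from the values, which lay between 4.17 and 13.51. Arrays within a sex had close medians (6.46 to 6.50 in males and 6.62 to 6.69 in females), but those of the sexes did not overlap, so the sexes did not share a distribution, and the reason is not given in the sources used here. No scan date, array batch or litter was named in the labels. Pups of a litter share dam and exposure, so the p-values may treat littermates as independent. The number of arrays, 5 per group, limits the precision of every estimate.

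Probe sets were named through the platform annotation, in which 18511 had 1 gene symbol (18166 distinct genes), 575 had several and 10403 had none. Tests ran on the 18511 probe sets with 1 symbol, with no filter on signal. Their Entrez identifiers matched the rat gene table of assembly GRCr8 for 18394, which was used only for the order of neighbouring genes. The build behind the annotation is not named, and no coordinates are given. Of the rows, 341 held values identical to those of another row. Correlations between arrays lay between 0.986 and 0.998, and no pair of arrays was identical.

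A linear model with 1 mean per group was fitted to all 20 arrays with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes prior. From it came the VPA effect in males, in females and averaged over the sexes, the interaction (male effect minus female effect), and the difference of males from females in saline and in VPA. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and every adjusted p of a gene is from this fit, except in the sex comparisons, where values and adjusted p are from the same model on arrays centred on their medians. Log2 fold changes are given with their standard error (SE), with n = 5 per group.

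Gene groups were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists within each comparison, on 1 probe set per gene, that with the highest mean. Of 41 lists covering synapses, cell types, neighbouring regions, development, signalling and metabolism, 40 had at least 4 measured genes. Camera with a correlation estimated per list, and fry, were run beside it. Each list's mean per array was compared by two-sided exact permutation tests within each sex and for the interaction, a test added after the list results had been seen. Across genes, Pearson and Spearman correlations of the male with the female effect were set against 100 draws with exposure labels shuffled within each sex.

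Apart from what is stated as added, the lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each sex, the 8 largest increases and 8 largest decreases past the threshold, filled by the smallest unadjusted p as values that did not pass. It took 5 and 5 for the average, the 5 smallest p for the interaction, and the members of the sex-linked lists with the 5 other smallest p, as deposited, for each sex comparison. For each list described it took up to 4 members with the smallest p. Symbols of unnamed loci and of the Olr, Vom1r and Vom2r families were counted but not named.

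On simulated data with the real means and spreads and independent genes, 67 of 18511 probe sets were changed 1.25-fold, 67 1.5-fold and 66 2-fold. The male comparison recovered 61.2% of those changed 1.25-fold and 97.0% of those changed 1.5-fold. For the female comparison these were 64.2% and 98.5%, and for the average 88.1% and 100%. The interaction recovered 22.4% and 76.1% in a second simulation, where other probe sets were changed in males only. Of 18311 unchanged probe sets in the first simulation, where both sexes changed alike, 7 were called in males, 9 in females, 6 in the average and 0 in the interaction. False calls of the interaction were not counted in the second simulation. Camera found a list shifted 1.25-fold in males (adjusted p = 2.7e-62) and called 0 of the other lists. The simulated genes were independent, so this says nothing of false calls in the real lists, whose estimated correlation had a median of 0.17.

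Alternatives changed 1 choice at a time, except for a threshold of unadjusted p under 0.05 with a minimum of 1.5-fold, which changed both: centring or quantile normalization of the arrays, filters on dim probe sets (the median of all probe sets, 6.56, or the 95th percentile of 70 olfactory receptor probe sets, 6.51), other rows or probe sets per gene, other variance priors, array weights, only the compared groups, the replicate number as a block, other thresholds, an ordinary test per probe set, and each array left out in turn. Covariates for tissue make-up and 2 subsets of arrays were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.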

Results

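Gene expression was measured in the prefrontal cortex of newborn rats exposed before birth to valproic acid (VPA) or to saline, in 20 arrays: 5 male saline, 5 male VPA, 5 female saline and 5 female VPA. The series asks about sex-specific effects of prenatal VPA, so the exposure effect was taken within each sex, averaged over the sexes and compared between them. The median log2 signal per array was 6.48 ± 0.02 (SD, n = 5) in male saline, 6.47 ± 0.01 in male VPA, 6.65 ± 0.03 in female saline and 6.64 ± 0.02 in female VPA. A signal of 6.51, the 95th percentile of 70 olfactory receptor probe sets with Olr symbols, was taken as background. Receptors with Or symbols, such as Or4c35 and Or9g19, were not among them. The value lay near the median of all probe sets, 6.56, and was the same for both sexes, so a signal below it does not show that a gene was absent. A gene is called dim where its mean over all 20 arrays lay below that value. Of the list members named, Nefh, Npas4, Myh11, Folr1 and Katnal2 were dim.

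In males, Rexo4, which encodes a putative exonuclease, had the smallest p, at a log2 fold change of 0.76 ± 0.12 (SE, n = 5 per group), but its adjusted p of 0.0628 missed the threshold. All 5 VPA arrays lay above all 5 saline arrays for it. C1h9orf85, at -0.80 ± 0.15, and Mmachc, a vitamin B12 processing gene, at 0.48 ± 0.09, both had an adjusted p of 0.113. The other positive values were C18h5orf63 at 0.69, Slc7a7, an amino acid transporter, at 0.46, Ndufb11b at 0.38, Mppe1 at 0.38, Tspan1 at 0.36 and B3galnt1 at 0.25. The other negative values were Sucnr1, the succinate receptor, at -0.65, Cdh20, a cadherin, at -0.43, Krt2 at -0.42, Castor2 at -0.42, Raver2 at -0.29, Gpr37 at -0.28 and Akap1 at -0.23. Krt2, Ndufb11b, Sucnr1 and Tspan1 were dim (Tspan1 read 6.17 in male saline and 6.53 in male VPA), and none of these genes passed the test.

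The list of striatal and subpallial genes, fixed as markers of a region next to the cortex, stood higher in male VPA as a group. All 20 measured members were positive, with a median log2 fold change of 0.46 (camera adjusted p = 7.7e-20), and 15 passed when adjusted over the list alone, but 0 when adjusted over all genes. Among them Penk, the enkephalin precursor, was at 0.77 ± 0.19, Six3 at 0.69 ± 0.19, Pdyn, the dynorphin precursor, at 0.64 ± 0.18 and Zfp503 at 0.61 ± 0.17. With an estimated correlation of its genes the list's call was lost (adjusted p = 0.20 with an estimated correlation).

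Smaller group shifts accompanied it in males. The GABAergic list was positive in 19 of 30 members with a median of 0.05 (adjusted p = 0.035), and 1 member, Calb1 at 0.30 ± 0.08, passed when adjusted over the list alone. Slc32a1, the vesicular GABA transporter, was at 0.32, Gabra4 at 0.32 and Dlx5 at 0.27. The cortical projection neuron list was negative in 25 of 30 members with a median of -0.11 (adjusted p = 0.00085), and Neurod6 at -0.20 ± 0.05 was its 1 member past the threshold when adjusted over the list alone. Neurod2 was at -0.19, while Foxp2 at 0.34 and Bcl11a at 0.15 were positive. The endothelial and pericyte list was negative in 19 of 22 members with a median of -0.07 (adjusted p = 0.042) and no member past the threshold adjusted over the list alone. Its smallest p belonged to Slc2a1 at -0.12, Tek at -0.16, Tie1 at -0.12 and Myh11 at -0.08. For each of these 3 lists the call was lost (adjusted p = 0.86 with an estimated correlation). It was also lost for the cortical list without male saline replicate 1 (-0.07, adjusted p = 0.070), and for the GABAergic and endothelial lists without any 1 of 5 and 6 of the 10 arrays, where medians came down to 0.02 without male VPA replicate 3 and -0.05 without male saline replicate 4. With the striatal mean as a covariate, chosen after seeing the data, the GABAergic median turned to -0.01 (adjusted p = 0.85) and the endothelial median was -0.02 (0.59). The cortical median shrank to -0.059 but kept its call (0.0058). Male VPA replicates 1 and 3, whose meningeal means were low, had the lowest endothelial means, 7.72 and 7.76 against 7.82 to 8.04 in the other male arrays. Without these and male saline replicate 2 the medians were -0.02 for the endothelial list (0.60) and 0.01 for the GABAergic list (0.23).

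In all, limma called 0 of 18511 probe sets in males, with 1281 at an unadjusted p under 0.05 where 926 would be expected by chance, and an ordinary test per probe set also called 0. Weighting the arrays called 14, and without the 3 male arrays with low meningeal genes (saline replicate 2 and VPA replicates 1 and 3, with list means of 7.83 to 7.995 where the other male arrays had 8.47 to 9.06) limma called 4, an alternative chosen after seeing the data. Leaving out 1 array gave 2 calls without saline replicate 2 and 1 call without VPA replicate 1 or 5.

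In females, 12 genes passed the test, of which 5 were higher and 7 lower with VPA. Rexo4 rose by 0.74 ± 0.12 (adjusted p = 0.0158). Dusp6, a phosphatase of the ERK kinases, rose by 0.43 ± 0.08 (adjusted p = 0.0328), the histone gene Hist1h2bq by 0.41 ± 0.08, the olfactory receptor Or4c35 by 0.31 ± 0.06 and Setsip by 0.23 ± 0.04, each with an adjusted p of 0.0371. Hist1h2bq and Setsip have near-identical copies elsewhere in the genome, so their probe sets could read several genes, and Or4c35 was dim. C1h9orf85 fell by 0.98 ± 0.15 and C9h6orf141 by 0.93 ± 0.14 (both adjusted p = 0.00542), Albfm1 by 0.90 ± 0.16 (0.0328), Ebpl by 0.85 ± 0.14 (0.0201), Tcp11 by 0.69 ± 0.09 (0.00234), Hint3 by 0.36 ± 0.06 (0.0060) and Crat, carnitine acetyltransferase, by 0.32 ± 0.06 (0.0499). Tcp11 was dim over all arrays, at 6.64 in female saline and 5.94 in female VPA. C1h9orf85 read 6.51 in female VPA (6.40 in male VPA) and C9h6orf141 6.19 in female VPA, at or below background, so the size of these 3 decreases may be limited. These readings lay well above the lowest value on any array, 4.17, and a limit was not tested. C9h6orf141 was measured by a pair of probe sets with identical values. Dhrs4 at 0.55, Gas2l3 at 0.59, Sgo1 at 0.37 and Cdpf1 at -0.46 did not pass (each adjusted p = 0.0544). The calls of C1h9orf85, C9h6orf141, Tcp11 and Hint3 held whichever array was left out. Rexo4 lost its call without VPA replicate 1 or 4, and the other 7 genes each without any 1 of 6 to 10 arrays, with adjusted p up to 0.145 for Crat without saline replicate 3.

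Genes of dividing cells stood higher in female VPA. The cell cycle list was positive in 31 of 37 members with a median of 0.10 (camera adjusted p = 2e-08), and 5 members passed when adjusted over the list alone, among them the proliferation marker Mki67 at 0.46 ± 0.13, Ccnd2 at 0.34 ± 0.10, Kif11 at 0.29 ± 0.09 and Uhrf1 at 0.23 ± 0.07 (adjusted p = 0.62 with an estimated correlation). The neural progenitor and radial glia list was positive in 19 of 25 members with a median of 0.09 (adjusted p = 2.6e-05), and 1 member, Egfr at 0.39 ± 0.10, passed when adjusted over the list alone (adjusted p = 0.55 with an estimated correlation). Nes, encoding nestin, was at 0.31 and Gli3 at 0.20, while Hes1 was at -0.18. No member of either list passed over all genes. Female saline replicate 5 had the lowest cell cycle mean of its group, 8.46 against 8.62 to 8.77, and without it the median was 0.05 (adjusted p = 0.0023). The progenitor median was 0.06 without that array (0.0029) and 0.05 without female VPA replicate 2 (0.00064). With the striatal mean as a covariate, chosen after seeing the data, the medians were 0.055 for the cell cycle (0.011) and 0.084 for progenitors (0.002). With the striatal, meningeal and choroid plexus means they were 0.054 (0.037) and 0.089 (0.00044).

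Of the other lists, those of cytoskeletal, cortical projection, axon guidance, autism risk and chromatin genes stood higher in female VPA, with medians between 0.06 and 0.08. The glutamatergic (0.03, adjusted p = 0.27), GABAergic (-0.02, 0.78), synaptic vesicle (0.02, 0.65) and voltage-gated channel (0.06, 0.055) lists did not pass. The cytoskeleton and neurite list was positive in 30 of 33 members (adjusted p = 8.1e-06; adjusted p = 0.75 with an estimated correlation), with Cntn2 at 0.25, Ank3 at 0.22, Map1b at 0.19 and Ina at 0.13. The cortical projection neuron list was positive in 22 of 30 members (0.00080; adjusted p = 0.75 with an estimated correlation), with Nfia at 0.23, Nfib at 0.23, Etv1 at 0.20 and Tbr1 at 0.16. The axon guidance list was positive in 22 of 34 members (0.012; adjusted p = 0.80 with an estimated correlation), where Sema3c at 0.31 ± 0.08 was the 1 member past the threshold adjusted over the list alone, Efnb2 was at 0.23, Slit2 at 0.19 and Efna2 at -0.13. The autism risk list was positive in 28 of 35 members (0.00087; adjusted p = 0.80 with an estimated correlation), with Tcf4 at 0.28, Tbr1 at 0.16, Katnal2 at 0.09 and Foxp1 at -0.19. The chromatin list was positive in 20 of 26 members (0.0024; adjusted p = 0.75 with an estimated correlation), with Smarca2 at 0.20, Chd4 at 0.19, Smarcc1 at 0.17 and Smarcc2 at 0.14. Adjusted over the list alone, no member of the cytoskeleton, cortical, autism risk or chromatin list passed. The cortical median ran from 0.04 without female saline replicate 2 (0.011) to 0.10 without female VPA replicate 2. Without female saline replicate 3 the medians were 0.04 for the cytoskeleton list, which kept its call (0.0019), and 0.03 for axon guidance (0.36), 0.04 for autism risk (0.13) and 0.04 for chromatin (0.075), which lost theirs. These 3 calls were lost without any 1 of 4, 3 and 2 of the 10 arrays, and also without both female saline arrays with high choroid plexus genes (0.21, 0.11 and 0.057). The cortical call was lost with the striatal, meningeal and choroid plexus means as covariates (0.06, adjusted p = 0.060), and both alternatives were chosen after seeing the data.

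The lists lower in female VPA by camera were striatal, choroid plexus and respiratory genes. The meningeal and fibroblast list had a larger median than the last 2, -0.28, with 16 of 20 members negative, but did not pass (adjusted p = 0.066). Of 20 striatal and subpallial genes 19 were negative, with a median of -0.41 (adjusted p = 6.8e-10), and 11 passed when adjusted over the list alone (adjusted p = 0.62 with an estimated correlation). Penk was at -0.77 ± 0.19, Pdyn at -0.65 ± 0.18, the dopamine receptor Drd2 at -0.55 ± 0.16 and Ppp1r1b at -0.41 ± 0.11. The oxidative phosphorylation list was negative in 38 of 41 members with a median of -0.08 (6.7e-05; adjusted p = 0.80 with an estimated correlation), with Ndufs7 at -0.20, Cox6a1 at -0.14, Cox8a at -0.14 and Ndufs1 at 0.10. The choroid plexus and ependyma list was negative in 13 of 15 members with a median of -0.13 (0.026; adjusted p = 0.80 with an estimated correlation). Its abundant gene Ttr, transthyretin, was at -1.78 ± 0.73, Folr1 at -0.33, Aqp1 at -0.23 and Kcne2 at -0.17. Ttr read 6.35 to 6.62 in 4 of the female VPA arrays, near background, so the size of its difference may be limited. Adjusted over the list alone, no member of either of these last lists passed. Female saline replicate 3 had a choroid plexus list mean of 7.17 against 6.39 to 6.70 in the other saline females, and without it the median was -0.05 (adjusted p = 0.55), or -0.02 without replicates 1 and 3 (0.91). That call was lost without any 1 of 4 arrays, while the oxidative phosphorylation median was -0.05 without female VPA replicate 5 (0.0077). Ttr read 10.04 in female saline replicate 1 and 12.30 in replicate 3, against 6.39 to 7.19 in the other saline females.

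The female count was 13 of 18511 probe sets, 5 higher and 8 lower, with 1643 at an unadjusted p under 0.05. Without female saline replicates 1 and 3, an alternative chosen after seeing the data, it was 5, and an ordinary test per probe set called 3. With the striatal mean as a covariate, also chosen after seeing the data, 7 passed, all lower, and each of the 5 increases lost its call (Rexo4 at 0.73, adjusted p = 0.147). The other increases were then at 0.39 for Dusp6, 0.33 for Hist1h2bq, 0.32 for Or4c35 and 0.22 for Setsip, against 0.43, 0.41, 0.31 and 0.23 without the covariate. Rexo4, Or4c35 and Setsip thus hardly moved, so their lost calls do not tie them to the striatal mean. Among the decreases, Albfm1 (-0.88, adjusted p = 0.293) and Crat (-0.25, 0.587) also lost their calls. C1h9orf85 (-1.07), Ebpl (-1.02), C9h6orf141 (-1), Tcp11 (-0.76) and Hint3 (-0.41) kept theirs, with larger decreases than without it. Leaving out 1 array gave 5 to 15, with 5 without VPA replicate 4, 6 without VPA replicate 1 or 3, 7 without saline replicate 3, and 8 without saline replicate 2 or VPA replicate 5.

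Averaged over the sexes, 59 genes passed the test. Rexo4 rose by 0.75 ± 0.09 (adjusted p = 0.000185), C18h5orf63 by 0.51 ± 0.10 (0.0176), the mitochondrial ribosomal gene Mrps10 by 0.50 ± 0.09 (0.0176), Arrdc3, an arrestin-domain gene, by 0.50 ± 0.08 (0.00894) and Trim59, a ubiquitin ligase, by 0.42 ± 0.06 (0.00491). C1h9orf85 fell by 0.89 ± 0.10 (0.000185), Albfm1 by 0.80 ± 0.12 (0.00439), Ebpl by 0.67 ± 0.10 (0.00491), C9h6orf141 by 0.56 ± 0.10 (0.0143) and Sucnr1, which was dim, by 0.50 ± 0.09 (0.0176). Mmachc (0.40, adjusted p = 0.00491) and Castor2 (-0.38, adjusted p = 0.0079) also passed here. C5h9orf85, which shares a name stem with C1h9orf85, fell by 0.27 ± 0.05 (0.0198), and their probe sets may not tell near-identical copies apart. For Rexo4 and C1h9orf85 the VPA and saline arrays did not overlap in either sex. C9h6orf141 was at -0.93 in females but at -0.19 in males (adjusted p = 0.912), so its average is mostly the female decrease.

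**Figure D1:**
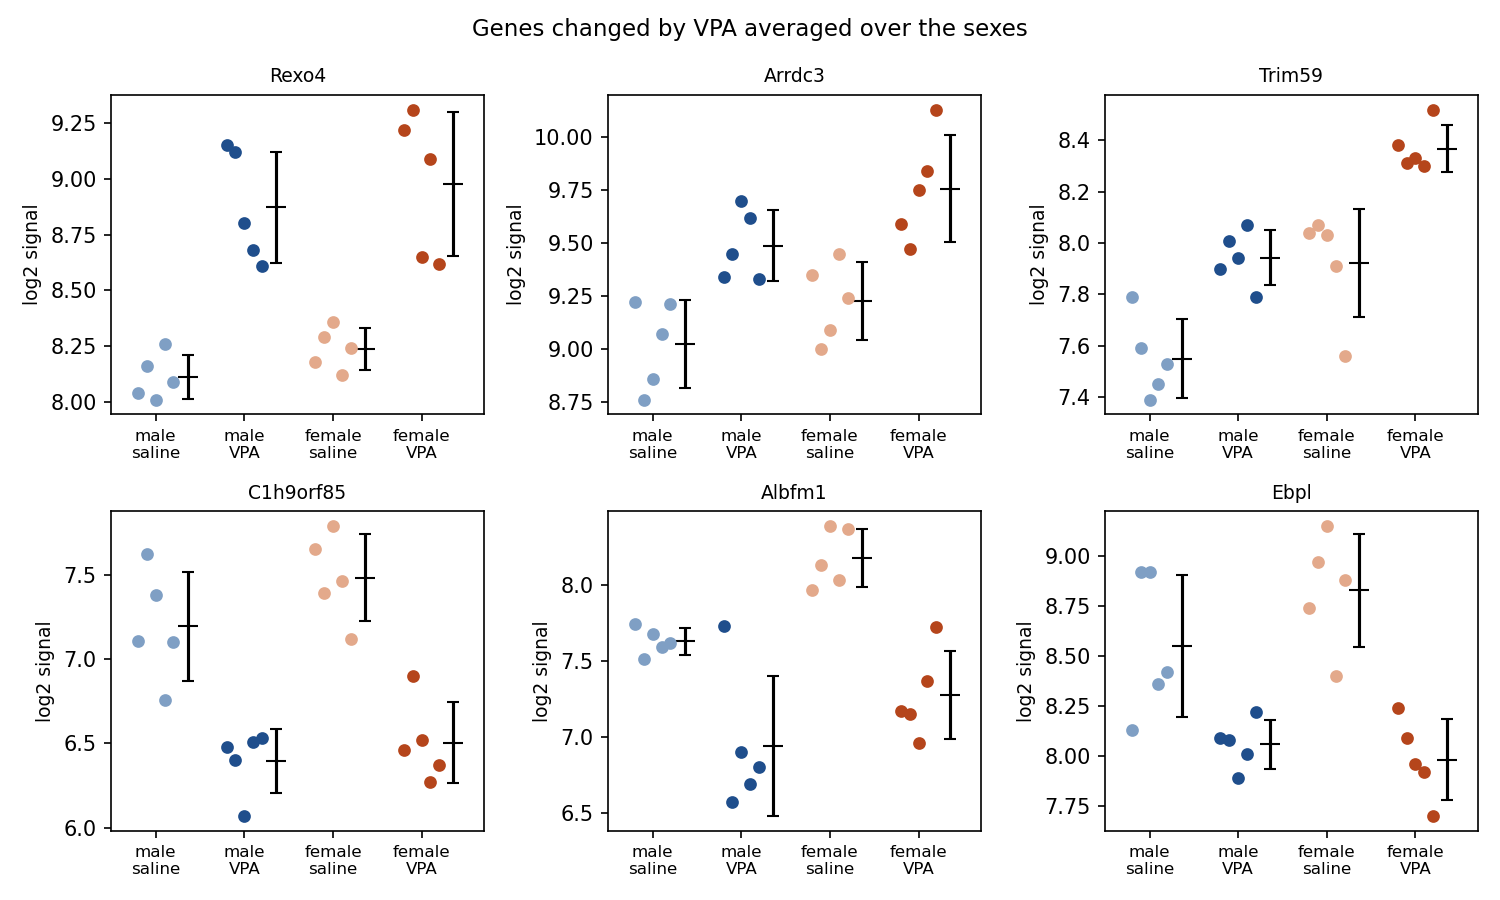
Log2 signal (vertical axes) of 6 genes changed by VPA averaged over the sexes, with 1 point per array in the 4 groups (horizontal axes) and bars giving the mean ± SD of 5 arrays. Rexo4, Arrdc3 and Trim59 stand higher with VPA in both sexes and C1h9orf85, Albfm1 and Ebpl lower, with 1 male VPA array at 7.73 for Albfm1 among the saline values.

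Among gene lists, 5 stood higher in the average and 0 lower. The cell cycle list was positive in 32 of 37 members with a median of 0.07 (camera adjusted p = 4.2e-07; adjusted p = 0.97 with an estimated correlation), led by Uhrf1 at 0.16, Mcm7 at 0.13, Mki67 at 0.25 and Nusap1 at 0.13. The neural progenitor list was positive in 22 of 25 members with a median of 0.06 (2.8e-05; adjusted p = 0.48 with an estimated correlation), led by Egfr at 0.23, Sox2 at 0.15, Nes at 0.21 and Id4 at 0.18. The cytoskeleton list was positive in 25 of 33 members (0.0068), with Ina at 0.11, Map1b at 0.11, Nefh at 0.10 and Cntn2 at 0.12. The axon guidance list was positive in 24 of 34 (0.0070), with Sema3c at 0.15, Efna5 at 0.16, Nrp2 at 0.27 and Efna2 at -0.09. The chromatin list was positive in 21 of 26 (0.023), with Smarcc2 at 0.09, Ezh2 at 0.08, Bmi1 at 0.11 and Smarca2 at 0.11. These last 3 calls were also lost (adjusted p = 0.97 with an estimated correlation). No member of the 5 lists passed over all genes or adjusted over the list alone. Without 1 array the cell cycle median came down to 0.04 (female saline replicate 5, adjusted p = 0.00062), and the cytoskeleton, axon guidance and chromatin calls were lost without any 1 of 3, 5 and 8 of the 20 arrays, with p up to 0.33 (male saline replicate 2), 0.18 (female saline replicate 3) and 0.20 (male saline replicate 2). These 3 calls were also lost with the 3 tissue means as covariates (0.084, 0.084 and 0.11), without the female arrays with high choroid plexus genes (0.088, 0.13 and 0.17) and without the male arrays with low meningeal genes (0.43, 0.12 and 0.28). The cytoskeleton median, 0.027, was then 0.025, 0.023 and 0.009. That of axon guidance, 0.061, was 0.033, 0.036 and 0.040, and that of chromatin, 0.052, was 0.028, 0.024 and 0.031. The cytoskeleton median thus hardly moved in the first 2 settings.

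The average comparison called 60 probe sets, 24 higher and 36 lower, with 1655 at an unadjusted p under 0.05, and 52 of the 60 had an unadjusted p under 0.05 in both sexes. The 60 were picked on the mean of both effects in these same arrays. That choice favours a small p in each sex, so the 52 is no replication between the sexes. Of the 13 female calls, 11 were among the 60. The average count was 27 without the female saline arrays with high choroid plexus genes, 37 without the male arrays with low meningeal genes and 111 with array weights.

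Whether the VPA effect differed between the sexes was tested as the male effect minus the female effect. Penk had the smallest p, at 1.55 ± 0.27, since it read 0.77 in males and -0.77 in females, but its adjusted p of 0.0815 missed the threshold. RT1-DOb, an MHC class II gene that read 6.40 in male saline, below background, was at 0.72 ± 0.12 (0.0815), and Tcp11 at 0.68 ± 0.13, Itpka, an inositol phosphate kinase, at 0.50 ± 0.09 and Impa2 at 0.46 ± 0.09 each had an adjusted p of 0.0948. The striatal and subpallial list had no negative interaction value among its 20 genes, and a median of 0.86 (camera adjusted p = 2.3e-27). Of its genes 17 passed when adjusted over the list alone, among them Lhx8 at 1.91 ± 0.42, Penk, Pdyn at 1.29 ± 0.26 and Ppp1r1b at 0.79 ± 0.16. Its call missed the threshold narrowly by camera (adjusted p = 0.061 with an estimated correlation) and passed by fry (adjusted p = 0.017).

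In a test added after the list results had been seen, the mean of the striatal list per array was 8.38 ± 0.36 (SD, n = 5) in male saline and 8.86 ± 0.11 in male VPA, a difference of 0.47 (two-sided exact permutation p = 0.0159). In females it was 9.13 ± 0.12 in saline and 8.73 ± 0.22 in VPA, a difference of -0.40 (exact permutation p = 0.0159). Adjusted over 40 lists, the exact p of these differences was 0.636 and 0.212. The difference between the sexes was 0.87 (exact permutation p = 0.000126, adjusted over 40 lists 0.00504), and no other list had an adjusted exact p under 0.05.

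**Figure D2:**
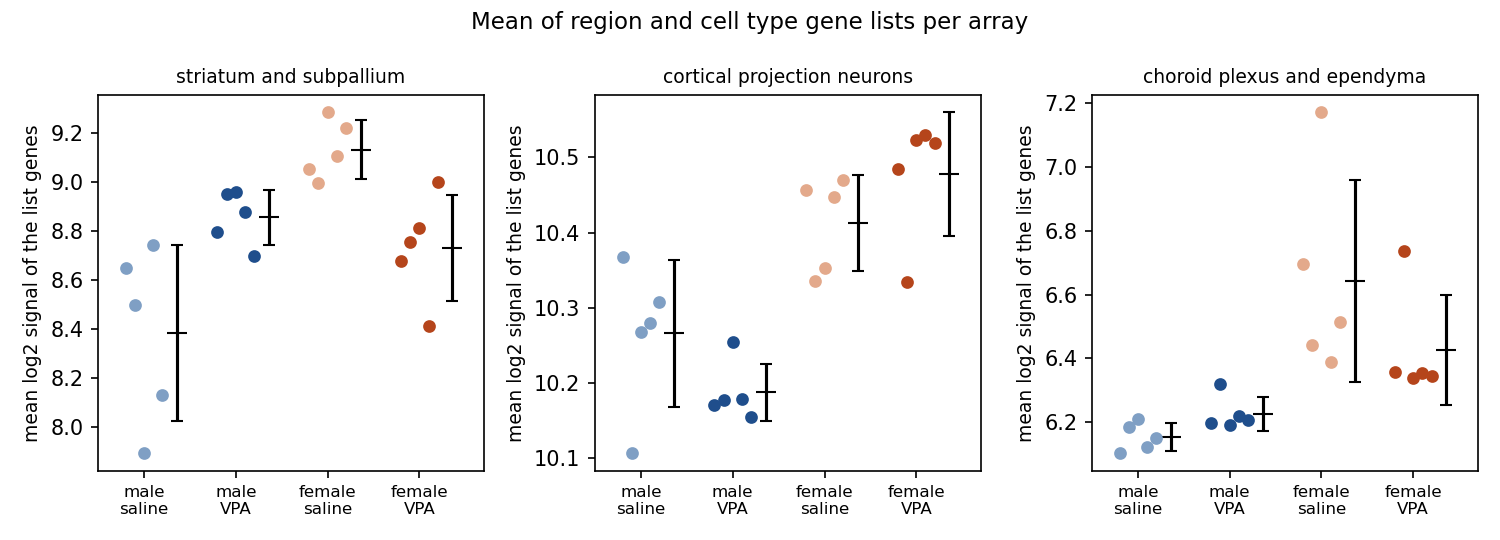
Mean log2 signal of the genes of 3 lists (vertical axes), with 1 point per array in the 4 groups (horizontal axes) and bars giving the mean ± SD of 5 arrays. The striatal mean is higher with VPA in males (8.86 against 8.38) and lower in females (8.73 against 9.13), the cortical projection mean is 10.19 against 10.27 in males and 10.48 against 10.41 in females, and the choroid plexus mean reaches 7.17 in female saline replicate 3.

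The other 11 lists with a camera interaction call had smaller medians, and each call was lost with an estimated correlation. The cortical projection list had a median of -0.21 (adjusted p = 1.8e-07; adjusted p = 0.42 with an estimated correlation), and adjusted over the list alone 6 members passed below 0 and 1 above, with Neurod6 at -0.25, Nfia at -0.33, Pou3f2 at -0.48 and Foxp2 at 0.54. The GABAergic list had a median of 0.04 (0.049) with 4 members past the threshold adjusted over the list alone, which were Slc32a1 at 0.59, Dlx6 at 0.57, Dlx5 at 0.44 and Calb1 at 0.40. The immediate early genes had a median of 0.07 (0.043) with 4 past the threshold adjusted over the list alone, of which Egr4 at 0.48, Npas4 at 0.36 and Dusp1 at 0.29 were positive and Dusp6 at -0.39 negative. Medians were 0.11 for oxidative phosphorylation (0.00041), 0.10 for fatty acid oxidation (0.035), 0.16 for choroid plexus (0.016), -0.06 for cytoskeleton (0.00056), -0.12 for autism risk genes (0.0023), -0.07 for cell cycle (0.0038), -0.10 for voltage-gated channels (0.045) and -0.07 for glutamatergic synapse genes (0.049), with no member of these 8 past the threshold adjusted over the list alone. Leaving out 1 array ended the call of 8 of these 11 lists at least once, with 10 of 20 arrays for the glutamatergic and GABAergic lists, 9 for the immediate early genes and the voltage-gated channels, 6 for fatty acid oxidation, 3 for autism risk, 2 for cell cycle (-0.01 without female saline replicate 5) and 1 for choroid plexus (0.08 without female saline replicate 3). The cytoskeleton median came down to -0.04 without male saline replicate 5 and that of oxidative phosphorylation to 0.07 without male saline replicate 1, both still past the threshold (0.014 and 0.035). With the striatal mean as a covariate the GABAergic median turned to -0.05 (adjusted p = 0.18) and that of the cell cycle to 0.07 (0.50), while the immediate early genes were at 0.06 (0.86) and choroid plexus at 0.08 (0.13). Other medians moved further from 0: glutamatergic -0.147 (0.00034), voltage-gated channels -0.185 (8.9e-05), autism risk -0.198 (9.4e-07), oxidative phosphorylation 0.172 (5.2e-06), fatty acid oxidation 0.142 (0.0011) and cytoskeleton -0.073 (0.0021). The cortical median was -0.17 (0.00021). Without the female saline arrays with high choroid plexus genes 6 calls were lost, those of the glutamatergic (0.23), GABAergic (0.092), voltage-gated channel (0.23), choroid plexus (0.28), autism risk (0.051) and fatty acid oxidation (0.24) lists. For the voltage-gated channels the adjusted p = 0.78 with an estimated correlation, and for the 9 others besides the cortical list the adjusted p = 0.72 with an estimated correlation.

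**Figure D3:**
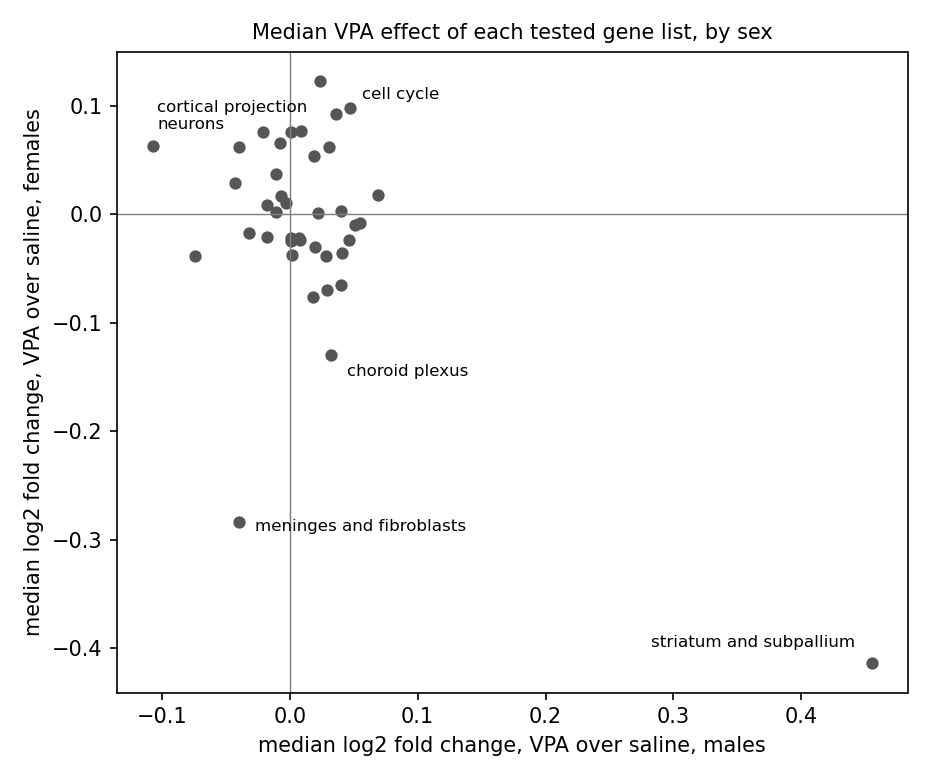
Median log2 fold change of VPA over saline in males (horizontal axis) and in females (vertical axis), with 1 point for each of 40 gene lists. The striatal and subpallial list lies apart at 0.46 in males and -0.41 in females, and grey lines mark 0.

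Limma called 0 of 18511 probe sets for the interaction, with 1110 at an unadjusted p under 0.05. The count was 19 without male saline replicate 4, 1 without male saline replicate 3 or female VPA replicate 5, 3 with each array centred and 1 with array weights.

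Across all 18511 probe sets the male and female VPA effects were barely related. Pearson's r was 0.064 and Spearman's rho 0.045 across genes, which are not independent replicates, and the signs matched for 50.8%. With exposure labels shuffled within each sex, 95% of 100 draws gave r between -0.46 and 0.43 (permutation p = 0.78). Among the 13 probe sets called in females r was 0.81 (permutation p = 0.069). They were picked on the female effect with the real labels and not anew in each shuffle, so this p decides nothing. Of the 13, 12 had the same sign in males, among them Rexo4 and C1h9orf85 but not Or4c35. Only 5 of the 13 had an unadjusted p under 0.05 in males. The 12 include Tcp11 at -0.01 and Dusp6 at 0.04 in males, and C9h6orf141 counts through a pair of identical probe sets.

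Between the sexes, the arrays of males and females did not share a distribution, so differences of level cannot be separated from processing. Centring an array removes a single offset, and differences in processing that act on single genes would remain. The centred differences of genes given below therefore cannot be separated from processing either. As deposited, the median of all genes was 0.18 lower in males in saline, and genes are reported relative to it, after each array was centred on its median. Genes were named by the smallest p as deposited, where nearly all calls were lower in males, and the genes named this way were all lower in males. Centred, Or9g19 was lower in males than in females by -0.58 ± 0.05 (adjusted p = 6.19e-07), Ttc19 by -0.44 ± 0.05, Ublcp1 by -0.40 ± 0.05, the protease inhibitor Csta by -0.32 ± 0.04 and Gcsam by -0.31 ± 0.04. In VPA, Or9g19 was at -0.62 ± 0.05, Ube2d2b at -0.43 ± 0.06, Id2, an inhibitor of differentiation, at -0.42 ± 0.06, Xkrx at -0.40 ± 0.05 and Csta at -0.30 ± 0.04. Of these, Or9g19, Csta, Gcsam, Ube2d2b and Xkrx lay below background in every group, and Id2 was dim over all arrays but at 6.59 in female VPA.

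Of the sex-linked lists, 1 probe set named for a Y-linked gene and 6 X-linked genes were measured. The probe set named for Uty, a Y-linked demethylase gene, read lower in males in VPA after centring, at -0.36 ± 0.10 (adjusted p = 0.023). In saline it was at -0.28 ± 0.10 (0.0686), and as deposited it passed in both (0.000307 and 0.00107). Its means of 8.15 and 8.17 in males and 8.59 and 8.70 in females were all far above background. A transcript of the Y chromosome alone would be near background in 1 sex. The signal is therefore not that of Uty alone, its difference is no result on Uty, and this probe set checks no sex label. Other Y-linked genes and Xist were not analysed here. Pbdc1 was lower in males at -0.31 ± 0.05 in saline (adjusted p = 0.000527) and -0.28 ± 0.05 in VPA (0.0019). Centred values in saline were -0.17 for Ddx3x, 0.20 for Usp9x, 0.08 for Med14, -0.02 for Zfx and 0.00 for Uba1, and in VPA -0.35, 0.01, -0.04, -0.16 and 0.00, none past the threshold.

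**Figure D4:**
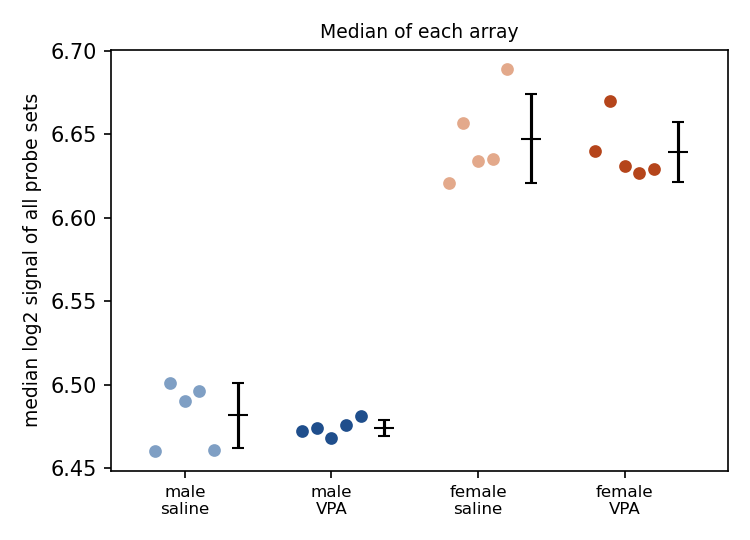
Median log2 signal of all probe sets (vertical axis), with 1 point per array in the 4 groups (horizontal axis) and bars giving the mean ± SD of 5 arrays. Male arrays lie between 6.46 and 6.50 and female arrays between 6.62 and 6.69.

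As deposited, 9746 probe sets differed between the sexes in saline, 263 higher and 9483 lower in males, and 8844 in VPA, 195 higher and 8649 lower. After centring these were 2963 (1542 higher, 1421 lower) and 2452 (1424 higher, 1028 lower). With quantile normalization they were 1957 (922 higher, 1035 lower) and 1817 (902 higher, 915 lower). Neither step would remove processing differences of single genes, so these counts cannot be read as sex differences alone.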

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

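Of the tests in this part, the neighbour test of called genes, the tissue covariates and the 2 array subsets were chosen after the results had been seen, as were the exact tests of list means, while the other tests were stated before their values were computed. The wording of the explanation by processing apart was changed after the centred counts had been seen, and 2 explanations without a usable test were dropped.

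The striatal and subpallial list stood higher with VPA in males and lower in females, with a median interaction of 0.86. If a varying share of striatal tissue in the dissected samples lay behind it, genes that follow the list within a group should also follow it between groups. The slope of each gene on the other list genes within groups and its interaction effect had a Spearman rho of 0.923 across 20 genes (permutation p = 1e-04, the smallest 10000 permutations can give). The genes are not independent (mean within-group correlation 0.487), and both values come from the same arrays, so this p is too small. Genes with a wider range would have a larger slope and a larger effect under any shared cause. A share of striatal tissue may account for the pattern, but the rho does not single it out. An effect of VPA on striatal neurons or their number that differs by sex would give the same gradient and stays open, untested. With the list's mean as a covariate the male shift of the GABAergic list became -0.01 and its interaction -0.05. That mean itself differed between VPA and saline, by 0.47 in males and -0.40 in females. The covariate would remove a shift that goes with it under either explanation, so these values decide nothing.

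For VPA averaged over the sexes 60 probe sets of 59 genes passed, and with the striatal, meningeal and choroid plexus means as covariates their median absolute log2 fold change went from 0.305 to 0.306 (100% kept), with 44 of the 60 still past the threshold and 16 not. Averaged over the sexes the 3 means differed by only 0.04, -0.13 and -0.07 between VPA and saline, so this outcome was nearly fixed beforehand, and differences in tissue make-up stay open. In an outbred strain litter genotype could place called genes next to each other if animals of a group shared litters, which the labels do not name. By gene order in assembly GRCr8, 9 of 59 called genes lay within 10 measured genes of another, against a median of 4 and a 95th percentile of 8 in 10000 random sets matched on expression, and 4.31% of random sets reached 9. Of the 5 neighbouring pairs 3 moved the same way (Mipep with Tnfrsf19, Tnfrsf19 with Ebpl, Mrap2 with Trim43a) and 2 did not (Hint3 with Echdc1, Ctrl with Lcat). Shared genotype predicts no direction, so these signs decide nothing. The excess was small, so shared genotype and an effect of VPA also stay open.

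Far more genes were lower in males than in females, at 97.3% of the calls in saline. After each array was centred the share was 48.0%, but centring removes an offset of any origin, so this value decides nothing between explanations. Processing of the arrays of the sexes apart, a batch that follows sex (none is named) and a true sex difference in total signal all stay open.

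Other splits of the same arrays were counted, with 100 drawn for each comparison, the real one included. They treat arrays as exchangeable, but exposure follows the dam and no litter is named. Chance differences between a few litters therefore cannot be excluded by these splits. For the 13 female calls only 1 split, the real one, gave as many, and the highest other gave 1. For the 60 averaged calls this was also 1, with the highest other at 51 in a split that exchanged 5 arrays, and the next at 5. For the sex comparisons it was 1 each, with 9746 against at most 3132 in saline, from a split that exchanged 1 array per group, and 8844 against at most 68 in VPA. That outcome was nearly fixed beforehand, since the array medians of the sexes did not overlap. With 0 calls in males and in the interaction every split gives as many (100 of 100), so the count of splits tests nothing there; the highest others were 3 and 4. For the list counts chance could not be excluded: 84 splits gave at least the 4 lists of males (highest other 19), 52 the 10 of females (24), 81 the 5 of the average (19) and 38 the 12 of the interaction (21). The other splits gave a median of 8 lists in males, 10 in females, 9 in the average and 9 in the interaction. Only the interaction count lay above its median.

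Besides the striatal list (0.86), 11 lists had a camera test of the sex difference past the threshold. All 12 calls were lost with an estimated correlation (smallest adjusted p = 0.061, for the striatal list). Median interactions of the 11 were -0.068 for glutamatergic synapse, 0.043 for GABAergic synapse, -0.10 for voltage-gated channels, -0.061 for cytoskeleton, -0.21 for cortical projection neurons, -0.068 for cell cycle, 0.16 for choroid plexus, 0.066 for immediate early genes, -0.12 for autism risk genes, 0.11 for oxidative phosphorylation and 0.10 for fatty acid oxidation.

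Of 220 groups of 5 values examined, 15 held an array far from the others, where chance gives about 1 in 20, or 11. The gap as a share of the group's range was 0.716 for Albfm1 and 0.725 for C1h9orf85 in male VPA (7.73 in replicate 1 and 6.07 in replicate 3), 0.764 for Cdpf1, 0.879 for Tcp11, 0.761 for Pbdc1 and 0.822 for Impa2 in female saline, 0.798 for Gpr37 in male saline, 0.801 for Itpka and 0.732 for Mppe1 in male VPA, and 0.760 for Mrps10 in female VPA. For list means it was 0.758 for cortical projection neurons in male VPA and 0.763 in female VPA, 0.750 for neural progenitors in female saline, and 0.792 and 0.958 for choroid plexus in male and female VPA, both in replicate 2.

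Probe sets that were unnamed or had several symbols were outside the comparisons. With every probe set tested, 2 of them passed for VPA in males, 11 in females and 27 in the average.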

How the results depend on the processing

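Counts of genes changed by VPA depended on the choices, and the cause was not tested. Over the alternatives, 1573 of 1750 estimates of named genes kept sign and call, 107 lost the call, 58 gained it and 12 reversed, and of 737 list results 540 kept it, 189 lost it and 8 reversed. In males, the count of 0 became 1 with each array centred, 1 with probe sets above the median, 1 with those above the olfactory receptor background, 3 with all rows of the table, 14 with array weights, 2 with only the groups compared, 20 at unadjusted p under 0.05 and 1.5-fold, and 1 at adjusted p under 0.1. In females, the count of 13 became 23 above the median, 23 above the olfactory receptor background, 24 with all rows, 22 with no intensity trend, 20 with a robust variance prior, 49 with array weights, 23 at unadjusted p under 0.05 and 1.5-fold, 7 at adjusted p under 0.05 and 1.5-fold, 29 at adjusted p under 0.1, and 3 with an ordinary test per probe set. The average count of 60 became 111 with array weights, 5 at unadjusted p under 0.05 and 1.5-fold, 4 at adjusted p under 0.05 and 1.5-fold, and 97 at adjusted p under 0.1. The interaction count of 0 became 3 with each array centred, 1 with array weights, 59 at unadjusted p under 0.05 and 1.5-fold, and 5 at adjusted p under 0.1.

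Between the sexes, the count in saline became 2963 with each array centred, 1957 with quantile normalization, 143 at unadjusted p under 0.05 and 1.5-fold, and 141 at adjusted p under 0.05 and 1.5-fold. In VPA these were 2452, 1817, 70 and 70. Signs reversed for sex-linked genes near 0. In saline, Med14 became 0.08 centred and 0.13 with quantile normalization, Zfx 0.06 with quantile normalization, and Usp9x -0.02 with array weights, -0.04 without male saline replicate 1, -0.01 without male saline replicate 5, -0.06 without female saline replicate 2 and -0.07 without female saline replicate 3, with the highest value, 0.11, without male saline replicate 2. In VPA, Uba1 became 0.00 centred and 0.01 with quantile normalization, and Usp9x 0.01 centred and 0.03 with quantile normalization.

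The replicate numbers did not pair arrays, since the correlations of same-numbered arrays lay between -0.455 and 0.448 and in no pair of groups were all 5 over 0.1. With the replicate number as a block, 2 genes were called in males, 11 in females, 42 in the average and 0 in the interaction, and the lists called were 4, 16, 5 and 11. With the correlation estimated per list, 0 lists were called in males, 0 in females, 0 in the average and 0 in the interaction, and with fry 0, 0, 0 and 1.

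The following alternatives were chosen after seeing the data. With the striatal mean as a covariate the female count was 7 (0 higher, 7 lower) and male lists 14, and with the striatal, meningeal and choroid plexus means as covariates the female count was 7 (1 higher, 6 lower), male lists 10 and lists in the average 2. With the striatal mean as a covariate the GABAergic list became -0.013 in males and -0.054 for the interaction, and the interaction became 0.073 for the cell cycle and 0.056 for immediate early genes. With all 3 covariates these were -0.017, -0.099, 0.061 and 0.038. Without the 2 female saline arrays with high choroid plexus genes the female count was 5, the average 27, lists in the average 2 and lists of the interaction 7. Without the 3 male arrays with low meningeal genes the male count was 4, the average 37, male lists 8 and lists in the average 2.

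Leaving out each array in turn, the count ranged from 0 to 2 in males, 5 to 15 in females, 42 to 69 in the average, 0 to 19 for the interaction, 8853 to 9638 between the sexes in saline and 7945 to 8297 in VPA. Lists ranged from 2 to 10 in males, 6 to 15 in females, 2 to 9 in the average and 6 to 16 for the interaction. The correlation between the sexes ranged from -0.081 without male saline replicate 2 to 0.18. An ordinary test and a fit of only the groups compared were not run for the average and the interaction.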

Other observations

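Of the lists without a camera call for VPA in males, in females or in the average, 6 are given here by their means. VPA inhibits histone deacetylases, and the mean of 23 deacetylase and acetyltransferase genes differed between VPA and saline by 0.02 in males (two-sided exact permutation p = 0.238) and 0.00 in females (0.952), with n = 5 per group. For 25 glutamatergic synapse genes the differences were -0.04 (0.50) and 0.03 (0.603), though camera called that list's interaction, for 7 chloride transporter genes 0.06 (0.302) and -0.02 (0.786), for 19 microglial genes -0.03 (0.611) and -0.01 (0.921), and for 40 inflammation genes 0.01 (0.770) and -0.03 (0.452). The 35 monoamine, oxytocin and vasopressin genes were lower in female VPA by -0.09 (0.0159, adjusted over 40 lists 0.212), and their difference between the sexes was 0.12 (0.0147, adjusted 0.294), so neither passed. Drd1 and Drd2 belong to this list and to the striatal list, at -0.45 and -0.55 in females and 0.43 and 0.30 in males. The list without them was not tested.

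The spread of neighbouring-tissue genes was wide within groups. The striatal mean ran from 7.89 in replicate 3 to 8.74 in replicate 4 of male saline and from 8.70 to 8.96 in male VPA. The meningeal mean of 20 genes was 8.53 ± 0.36 (SD, n = 5) in male saline and 8.53 ± 0.57 in male VPA, and 8.91 ± 0.19 and 8.65 ± 0.35 in females.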
